A study of Mus musculus with 4 samples.

How the data were processed

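The series holds 4 libraries from sorted islet T cells of pre-diabetic female NOD mice: 1 messenger RNA library and 1 T cell receptor library at 8 weeks and the same at 16 weeks of age. Per the labels' protocols, live TCR beta-positive cells were sorted with DAPI as the dead cell stain and processed with droplet-based single-cell 5' reagents. The authors deposited UMI counts per gene and cell barcode as whole numbers, not normalized, for 27998 genes, and per the file headers the matrices are in the Cell Ranger layout. Contig tables of the receptor libraries give, per the file headers, the V and J segments, the CDR3 sequence, and the counts of reads and UMIs of each assembled chain. Mouse build mm10 and Seurat are named in the submitters' processing notes, and Seurat's role, the aligner, the gene annotation and any filter on barcodes are not given in the sources used here. Gene coordinates were taken by Ensembl identifier from GENCODE M21, an annotation of the same mouse build. Age was taken from the labels, and the receptor and RNA libraries of 1 age were joined by cell barcode.

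Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, leidenalg 0.10.2 and matplotlib 3.10.9 were used. Cells with 500 or more genes and 10% or less mitochondrial UMIs were kept: 136 and 151 barcodes had too few genes and 32 and 22 too high a mitochondrial share at 8 and 16 weeks. Scrublet, run per library with an expected doublet rate of 0.02, marked 3 of 3809 cells (0.0788%), which were removed, so doublets were in effect not removed. At least 2 productive beta chains, a sign of doublets or of dual receptors, were found in 202 of 1581 kept cells with a beta chain at 8 weeks (12.8%) and in 234 of 1641 at 16 weeks (14.3%), and these cells were kept in the main values and left out in an alternative. The 3806 cells of both libraries were clustered together: counts scaled to 10000 per cell and log-transformed, 2000 variable genes without receptor, ribosomal, mitochondrial and Xist genes, 30 principal components, 15 neighbours and Leiden resolution 1.

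This gave 15 clusters, named from marker genes fixed before the data were examined. The scoring was set after the clusters were seen: 3 or more markers among the top 50 genes by fold, no detected marker of that type below a log2 ratio of -0.58, and no other type with more markers among the top 10. Clusters led by Lef1 and Ccr7 or by Klf2 were called naive or stem-like T-like, and those led by Foxp3 and Ctla4 or by Gpr83 and Il2ra regulatory T-like. Others were follicular helper T-like (Sostdc1, Cd200, Il21), CD8 T-like (Ccl5, Gzma, Gzmk), interferon-responding-like (Ifit3, Isg15) and proliferating-like (Hist1h2ap, Birc5). Another 5 clusters, with 515 and 505 cells, stayed unnamed, among them 1 led by Cd8b1 and Cd8a and 1 led by Fcer1g and Ncr1. An acinar-like cluster (40 and 55 cells, Ctrb1 and Prss2) and a B-like cluster (8 and 3 cells, Cd74 and Cd79a) were excluded from the T cells, leaving 1827 and 1873, a step also set after the clusters were seen. Many excluded cells carried T cell RNA or receptors, so T cells with acinar RNA may be among them. In the acinar-like cluster 40 of 95 cells had the UMIs of the Cd4 gate and 9 those of the Cd8 gate. Cells with a paired receptor went from 1362 and 1394 to 1336 and 1354 with this step. Shares of clusters describe the cells that were summed and are not given as results of age, since the genes that define the clusters differ between the libraries.

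Classes of T cells were gated on UMIs of Cd4, Cd8a, Cd8b1 and Foxp3. The conventional Cd4-gated class had 579 and 566 cells (2676400 and 2238270 UMIs), the Cd8-gated class 294 and 314 (1379976 and 1323466 UMIs), and the class of Cd4-gated cells with a Foxp3 UMI or in a regulatory T-like cluster 176 and 154 (1209384 and 1052069 UMIs). UMIs were summed over each class and divided by the class total to give CPM with exact 95% Poisson intervals. Log2 ratios added 0.5 UMIs to each sum, their intervals are exact and conditional on the gene's total, and a gene with no UMI on 1 side was set at 3 UMIs where a bound is given. Shares have Clopper-Pearson intervals and differences of shares Newcombe intervals; where a share is 0, the limit given in the text is 3 cells of the total, which lies below the exact limit. A difference between single libraries compares those libraries, not ages in general.

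Gene lists were fixed before the data were examined, as were the main alternatives, the classes and the rule for named genes. The 13 lists of cell states were stem-like and naive, exhaustion, anergy, Th1, Tfh, Th17, Treg, cytotoxic, tissue residency, proliferation, type I interferon response, immediate early and stress, and T cell costimulation and cytokine. The 8 lists of other cells were islet endocrine, acinar, B cell, myeloid, dendritic, endothelial and stromal, erythroid, and NK, NKT and gamma-delta T. Of 220 list members 213 were found by symbol, and Znf683, Ighm, Iglc2, Igkc, Trdc, Tcrg-C1 and Trdv4 were not used. Cxcr6 is in both the Th1 and the tissue residency list. The value of a list is the median log2 ratio over members with 10 or more UMIs in the compared cells, given for lists with at least 3 such members, with an interval from 1000 Poisson resamples and its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. The median over all measured genes was -0.05 in conventional Cd4-gated and -0.06 in Cd8-gated cells.

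Named genes were, per class, the 10 highest and 10 lowest log2 ratios of 16 over 8 weeks among genes with 100 or more UMIs, 50 CPM or more in 1 library, a UMI in 5% or more of cells in 1 library, and the same direction in the mean of per-cell CPM. Receptor, mitochondrial, ribosomal, Gm and Rik genes, Xist and genes of the lists of other cells were left out of this ranking. Always named were Tcf7, Slamf6, Pdcd1, Tox, Lag3, Izumo1r, Nt5e, Foxp3 (absent from conventional Cd4-gated cells by construction) and Ifng, and from each further list the 2 to 4 members with the most UMIs. Further members, such as Cxcr5, Il21, Mki67, Ccl3, Nr4a1, Tnf, Il2ra and Cd40lg, were chosen after their values were seen, as was the share of a gene's UMIs that 1 cell gave.

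A clonotype is the V segment and CDR3 nucleotide sequence of both chains, taking the chain with the most UMIs. Shares of cells in clones of 2 or more cells were means over 1000 draws of equal numbers of cells per library where a difference is given. The all-T share was added after the data were seen. The steps that compute log2 ratios and list medians were tested on simulated counts, with 100 genes changed each way by a log2 of 1. Mean recovered ratios were 1.01 and -0.94 in conventional Cd4-gated cells (4931 genes; 96.0% and 94.0% of intervals held the true value) and 1.00 and -0.96 in Cd8-gated cells (3107 genes; 98.0% and 97.0%). Simulated lists of 13 genes changed by 1 gave medians of 1.01 (9786 genes) and 1.02 (8831 genes). The simulated counts followed the Poisson model that the intervals assume. Their coverage therefore does not show how the intervals hold where 1 cell gives much of a gene's UMIs.

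Alternatives chosen before the data were examined were no cell filter, a stricter filter (1000 genes and 5% mitochondrial UMIs), doublets kept, lineage from clusters, equal weight per cell, median-ratio scaling, members with 50 or more UMIs, each list member left out, all Cd4-gated cells, no thinning, the regulatory T-like cluster share, clonotypes from the beta chain or from amino acids, clones of 3 or more cells, and all cells without equal draws. Alternatives added after the data were seen were lineage from the majority of Cd4 and Cd8 UMIs, leaving out cells with 2 or more beta chains, leaving out cluster 5 (71 and 221 cells) or cluster 11 (21 and 23 cells, led by Clu and Spp1), and removing library means before clustering.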

Results

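T cells were profiled from the pancreatic islets of female NOD mice, a strain that develops autoimmune diabetes spontaneously, at 8 and at 16 weeks of age, when the animals were not yet diabetic. Live cells carrying the T cell receptor beta chain were sorted at each age and gave 1 messenger RNA library and 1 T cell receptor library per age, 4 libraries in all. With 1 library of each kind per age there are no replicates: no difference between the ages was tested, and every interval covers counting error only. The 8-week RNA library held 2043 cell barcodes and 8659371 UMIs (unique molecular identifiers, each counting 1 captured RNA molecule), and the 16-week library held 2107 barcodes and 8183747 UMIs. After filtering, 1875 and 1931 cells remained, with medians of 2975 and 2928 UMIs and of 1167 and 1127 genes per cell. A paired alpha and beta receptor chain was found in 1362 (72.6%) and 1394 (72.2%) of these cells. The series title asks about stem-like T cells and about the resistance of CD4 T cells to exhaustion, and the series design sets the 8-week against the 16-week transcriptome.

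Cells with a Cd4 UMI and no Cd8a or Cd8b1 UMI are called Cd4-gated, and cells with the opposite pattern Cd8-gated. Conventional Cd4-gated cells also had no UMI of Foxp3, the transcription factor that defines regulatory T cells, and lay outside the regulatory T-like clusters. Gene levels are sums of UMIs over the cells of a class, as counts per 1000000 UMIs of the class (CPM), and ratios are on the log2 scale. Among the genes named, Tcf7 (ENSMUSG00000000782) lies on chromosome 11 from 52252371 to 52283014 of mouse build mm10, and Slamf6 (ENSMUSG00000015314) on chromosome 1 from 171917515 to 171953170. Pdcd1 (ENSMUSG00000026285) spans 94038305 to 94052553, also on chromosome 1. Tox (ENSMUSG00000041272) lies on chromosome 4 from 6686353 to 6991557, and Lag3 (ENSMUSG00000030124) on chromosome 6 from 124904361 to 124911705. Izumo1r (ENSMUSG00000031933) spans 14885814 to 14903949 and Nt5e (ENSMUSG00000032420) spans 88327197 to 88372092, both on chromosome 9. Foxp3 (ENSMUSG00000039521) lies on chromosome X from 7573644 to 7595245, and Ifng (ENSMUSG00000055170) on chromosome 10 from 118441046 to 118445892.

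Cd4-gated cells made up most of the islet T cells that could be assigned to a lineage at both ages. They were 755 of 1049 such cells at 8 weeks (72.0%, exact 95% binomial interval 69.2 to 74.7%) and 720 of 1034 at 16 weeks (69.6%, 66.7 to 72.4%). The difference was -2.34 percentage points, with a Newcombe interval for counting error (-6.24 to 1.56) that held values of both signs. With the lineage taken from clusters the difference was 1.05 points, with the stricter cell filter -0.452 points, without cluster 5 -3.62 points, and without cells that had 2 or more beta chains -4.39 points (-8.60 to -0.169). The gate assigned 57.4% and 55.2% of the T cells, because a Cd4 UMI was found in only 45.7% and 43.0% of them. Foxp3 was detected in 48 of 697 Cd4-gated cells at 8 weeks (6.89%, 5.12 to 9.03%) and in 48 of 693 at 16 weeks (6.93%, 5.15 to 9.08%), when each cell was thinned to 1700 UMIs and 58 and 27 shallower cells were left out. Cd8-gated cells, most of which should lack Foxp3, gave 2.47% and 2.67% at the same depth. Without thinning the Foxp3 shares of Cd4-gated cells were 15.2% and 12.4%, a difference of -2.87 points, against 5.10% in Cd8-gated cells at both ages, with median depths of 3350 and 3269 UMIs in Cd4-gated and 3378 and 3260 UMIs in Cd8-gated cells. Regulatory T-like clusters held 17.2% and 17.8% of Cd4-gated cells.

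Conventional Cd4-gated cells at 16 weeks had more RNA of genes of naive and stem-like T cells and less of genes linked to exhaustion than those at 8 weeks. Lef1, a transcription factor of naive T cells, stood at 447 against 207 CPM (log2 ratio 1.11), and Klf2, which maintains T cell quiescence and trafficking, at 756 against 444 CPM (0.77). Satb1, a chromatin organiser, stood at 105 against 46.7 CPM (1.17). Il7r, the interleukin 7 receptor, was higher at 16 weeks by 0.45 and Ccr7, a lymph node homing receptor, by 0.38. Tcf7, which encodes the stem-like state regulator TCF-1, differed by 0.18 (0.01 to 0.35), and Slamf6, a surface marker of stem-like T cells, by -0.15 (-0.36 to 0.05). Of the 13 stem-like and naive genes, 10 were higher at 16 weeks and 3 lower, with a median of 0.38 (0.26 to 0.51), above the medians of all 10000 random lists matched on expression. When each cell was given equal weight, in place of summing UMIs, that median was 0.13. The genes of random lists were drawn independently. Percentiles among them thus take no account of genes that vary together or of variation between libraries.

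Among the exhaustion genes, the inhibitory receptor gene Pdcd1 (PD-1) stood at 132 CPM at 16 weeks against 192 at 8 weeks (-0.54), and Lag3 at 127 against 189 (-0.57). Tigit, a further inhibitory receptor gene, stood at 106 against 165 CPM (-0.64), Cd200 at 161 against 247 (-0.62), and Tox, a transcription factor that sustains exhaustion, at 78.6 against 107 (-0.45). Ctla4 differed by 0.09, and Havcr2 (TIM-3) had 4 and 6 UMIs in the class. Of 15 measured exhaustion genes 10 were lower and 5 higher, with a median of -0.32 (-0.53 to -0.13) at percentile 0.26 of the random lists. Of the anergy genes, 5 were higher and 5 lower, with a median of 0.01 (-0.19 to 0.16) and Dgka, a brake on receptor signalling, at 0.16. Izumo1r and Nt5e, which encode the anergy markers FR4 and CD73, differed by -0.15 (-0.29 to -0.02) and -0.28 (-0.72 to 0.15). The cells of the class were distributed over the clusters unequally: 29.4% at 8 weeks and 45.6% at 16 weeks were naive or stem-like T-like, and 32.3% and 23.7% were follicular helper T-like. Cd200 and Tox2 of the exhaustion list were also among the leading genes of the follicular helper T-like cluster. Of the 2 naive or stem-like T-like clusters, the one led by Klf2 held 71 cells of all classes at 8 weeks and 221 at 16 weeks.

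**Figure D1:**
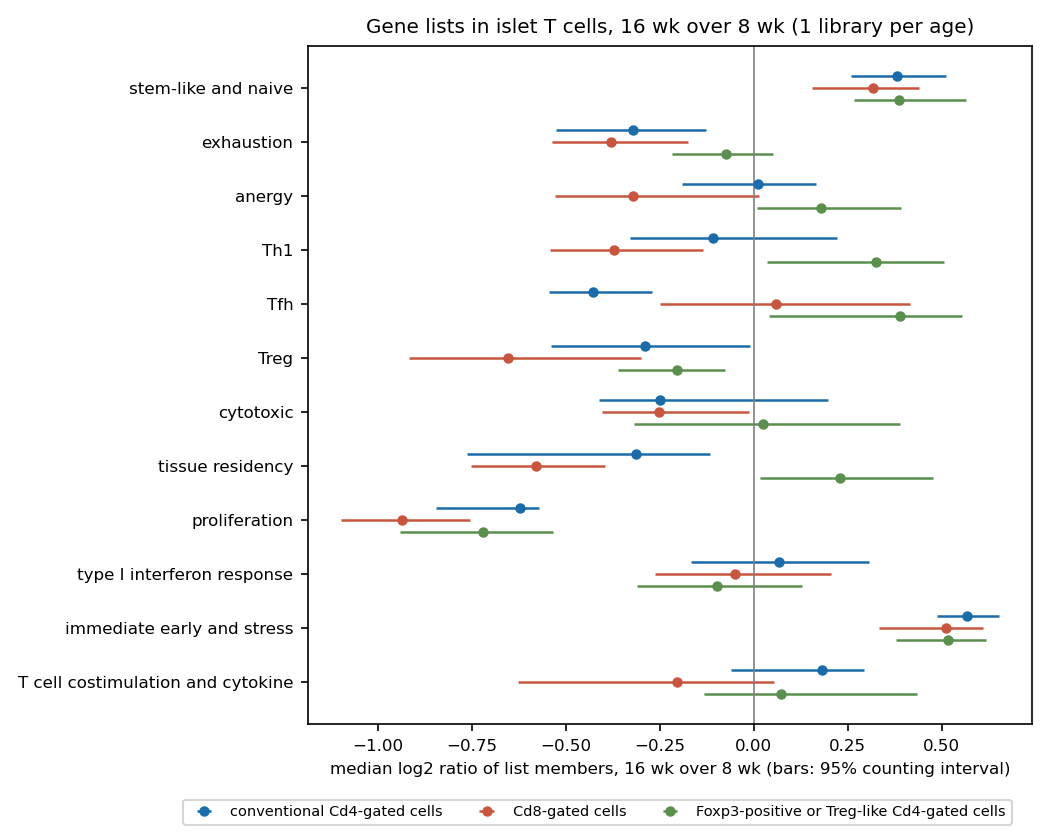
Median log2 ratio of 16 over 8 weeks for 12 gene lists (vertical axis) in conventional Cd4-gated, Cd8-gated and Foxp3-positive or regulatory T-like Cd4-gated cells; points are medians over list members and bars are 95% counting intervals. The stem-like and naive list lies at 0.38, 0.32 and 0.39 in these classes, and the proliferation list at -0.62, -0.94 and -0.72.

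Genes of cell division and of follicular helper T cells were also lower in the 16-week conventional Cd4-gated cells, and immediate early and stress genes were higher. All 12 proliferation genes were lower, with a median of -0.62 (-0.85 to -0.57), among them Hmgb2 (565 against 859 CPM), Tubb5 (-0.21), Stmn1 (204 against 307) and Mki67 (26.4 against 60.5). Of 10 follicular helper genes 8 were lower, with a median of -0.43 (-0.55 to -0.27): Sh2d1a, needed for T cell help to B cells, stood at 235 against 315 CPM, Tnfsf8 at 123 against 143, Maf at 87.1 against 118, and Cxcr5, the follicle homing receptor, at 24.1 against 40.7. Sostdc1, a gene that named the follicular helper T-like cluster, was higher at 16 weeks. It had 28 UMIs at 8 weeks, against 76 at 16 weeks in the cells whose receptor was seen once, a part of the class. A single cell gave 43.4% of those 76. All 12 immediate early and stress genes were higher at 16 weeks, with a median of 0.57 (0.49 to 0.65); the heat shock gene Hspa1b differed by 0.64, Junb by 0.49 and Jun by 0.67. RNA of pancreatic acinar cells was higher too: all 8 measured acinar genes, led by Clps (44 against 25 UMIs) and Ctrb1 (43 against 25), with a median of 0.76 (0.38 to 1.26). In whole libraries, before filtering, the trypsinogen gene Prss2 stood at 418 CPM at 16 weeks and 65.0 CPM at 8 weeks, and the ribosomal RNA-overlapping transcript Gm42418 took 4.97% and 3.29% of the UMIs. The insulin gene Ins2 went the other way, at 5.62 CPM (46 UMIs) at 16 weeks and 27.7 CPM (240 UMIs) at 8 weeks.

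Effector genes of conventional Cd4-gated cells went both ways. The chemokine receptor gene Cxcr3, typical of Th1 cells, stood at 78.6 CPM at 16 weeks against 133 at 8 weeks (-0.76), Stat4 at 73.7 against 114 (-0.62) and Ifng, the interferon gamma gene, at 44.2 against 55.3 (-0.32, -0.70 to 0.06). The chemokine genes Ccl5 (467 against 266 CPM), Ccl4 (153 against 43.0) and Ccl3 (33.1 against 4.11) were higher at 16 weeks. A single 16-week cell gave 71.1% of the Ccl4 UMIs and 77.0% of the Ccl3 UMIs, and 32 cells held all of the Ccl5, against 40 at 8 weeks. The class held 19 CD8 T-like cells at 8 weeks (3.28%) and 15 at 16 weeks (2.65%). Ccl5 and Gzmk were among the markers that named that cluster, and whether these cells carried the UMIs of both genes was not examined. The 11 measured Th1 genes had a median of -0.11 (-0.33 to 0.22). Cytotoxic genes had a median of -0.25 (-0.41 to 0.20), with Nkg7 at -0.36, Ctsw at -0.35 and Gzmk, a granzyme gene, at 1.08, although fewer cells carried it at 16 weeks (26) than at 8 weeks (35). The tissue residency list had a median of -0.31 (-0.76 to -0.12), in which Rgs1 differed by -0.21, Cxcr6 by -0.77 and the activation marker Cd69 by 0.52. Interferon response genes had a median of 0.07 (-0.17 to 0.31), with Ifi27l2a at -0.24 and Bst2 at 0.30, and costimulation and cytokine genes had a median of 0.18 (-0.06 to 0.29), with Cd28 at 0.23 and Cd27 at 0.08. Genes of the regulatory T cell list other than Foxp3 had a median of -0.29 (-0.54 to -0.01), with Tnfrsf4 at -0.43, Tnfrsf18 at -0.10 and Ikzf2 at -0.71.

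Genes with the highest ratios in conventional Cd4-gated cells included Satb1, Lef1 and, carried by few cells, Gzmk and Ccl5. Among the others were Myc, a driver of cell growth (74.6 against 36.2 CPM, log2 ratio 1.04), Dapl1 (1.01), the phosphatase gene Dusp1 (0.97), the guanylate-binding protein gene Gbp8 (0.86) and Vps37b (0.85). The 10 lowest were led by Lgals3, the galectin-3 gene, at 20.6 against 69.9 CPM (-1.75, -2.26 to -1.29). Of the others, 6 are genes of DNA replication or chromatin: Hist1h2ap (-1.44), Rrm2 (-1.30), Hist2h2bb (-1.23), Cenpw (-1.21), Mki67 (-1.19) and Tyms (-1.17). A single 8-week cell gave 51.9% of that library's Hist2h2bb UMIs, which were those of the gene copy with the identifier ENSMUSG00000105827. S100a4 and Anxa2, which are higher in effector and memory T cells than in naive ones, stood at 49.6 against 112 CPM (-1.17) and at 140 against 295 CPM (-1.07), and Bcap29 at -1.06.

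**Figure D2:**
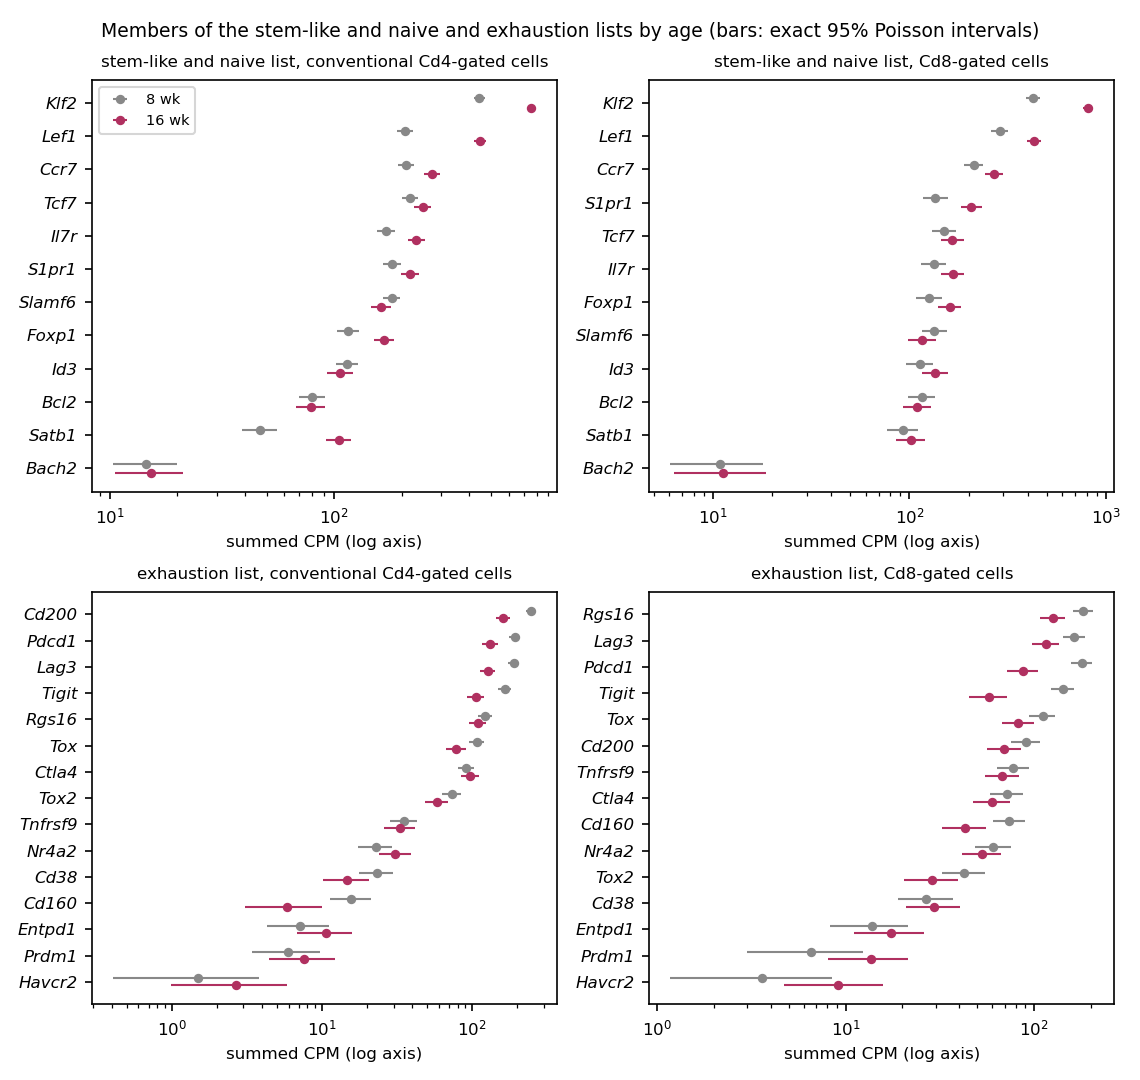
Summed CPM (horizontal log axis) of genes of the stem-like and naive list (top) and the exhaustion list (bottom) in conventional Cd4-gated (left) and Cd8-gated cells (right) at 8 and 16 weeks; points are values of 1 library and bars are exact 95% Poisson intervals. Klf2 lies at 444 and 756 CPM in conventional Cd4-gated and at 427 and 811 CPM in Cd8-gated cells.

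Cd8-gated cells (294 at 8 and 314 at 16 weeks) also had more RNA of naive-type genes and less of exhaustion and effector genes at 16 weeks. Klf2 stood at 811 against 427 CPM (0.93) and S1pr1, which lets T cells leave tissues, at 207 against 136 (0.61), while Tcf7 differed by 0.13 (-0.15 to 0.42) and Slamf6 by -0.20 (-0.52 to 0.11). Pdcd1 stood at 86.9 against 179 CPM (-1.04), although 1 cell gave 19.1% of its 16-week UMIs, Tigit at 57.4 against 142 (-1.30), Lag3 at 116 against 163 (-0.49) and Tox at 82.4 against 111 (-0.43). Of 13 stem-like and naive genes 11 were higher, with a median of 0.32 (0.15 to 0.44; above all 10000 random lists), and of 15 exhaustion genes 11 were lower, with a median of -0.38 (-0.54 to -0.17; percentile 0.04). With the lineage taken from clusters the exhaustion median was -0.16 (-0.33 to 0.12). CD8 T-like cells were 28.6% of the class at 8 weeks and 16.6% at 16 weeks, and cells of unnamed clusters, mostly 1 led by Cd8b1, Cd8a and Tmem108, were 55.4% and 66.6%.

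Genes of cytotoxic effector cells and of cell division were among the lowest at 16 weeks in Cd8-gated cells, and few cells carried the granzyme genes Gzma and Gzmb. Gzma stood at 17.4 CPM at 16 weeks against 162 at 8 weeks (-3.20, -3.91 to -2.60), with UMIs in 4 and 15 cells, and Gzmb at 22.7 against 111 CPM (-2.27), with UMIs in 11 and 16 cells. The other genes among the 10 lowest were S100a4 (-2.34), S100a6 (369 against 1353 CPM, -1.87), Lgals3 (-1.77), Tigit and the cell division genes Hist1h2ap (-1.75), Top2a (-1.72), Ube2c (-1.49, with 34.5% and 51.4% of its UMIs at 8 and 16 weeks from 1 cell) and Tk1 (-1.23). The 10 highest were Pik3ip1, an inhibitor of PI3 kinase (60.5 against 23.9 CPM, 1.33), Alkbh5, an RNA demethylase gene (1.05), Nr3c1, the glucocorticoid receptor gene (0.97), Wdr55 (0.95), Klf2, Zfp36l2 (0.88), Dusp1 (0.83), Cd69 (0.83), Fos (0.82) and Ccdc117 (0.81). All 12 proliferation genes were lower (median -0.94, -1.10 to -0.76), with Hmgb2 at -0.73, Tubb5 at -0.03 and Stmn1 at -0.84. Of 7 tissue residency genes 6 were lower (median -0.58, -0.75 to -0.40), with Rgs1 at -0.51 and Xcl1 at -0.63. Th1 genes had a median of -0.37 (-0.54 to -0.14), with Cxcr3 at -0.87, Ifng at -0.37 and Ccl5, at 4664 against 4916 CPM, at -0.08. Ccl4 had 322 UMIs at 16 weeks and 446 at 8 weeks, of which a single 8-week cell gave 46.0%.

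The remaining lists in Cd8-gated cells had medians of -0.25 (-0.41 to -0.01) for cytotoxic genes, -0.32 (-0.53 to 0.01) for anergy genes and -0.65 (-0.92 to -0.30) for the regulatory T cell list. In these lists Nkg7 differed by -0.37, Ctsw by -0.51, Dgka by 0.04, Izumo1r by -0.24, Nt5e by -0.41, Tnfrsf18 by -0.26 and Ikzf2 by -0.44. Foxp3 stood at 20.4 against 20.3 CPM. Regulatory T-like cells were not removed from this class and were 4.42% of it at 8 weeks and 2.55% at 16 weeks. Follicular helper genes had a median of 0.06, interferon response genes of -0.05 and costimulation genes of -0.20, with Sh2d1a at -0.07, Ifi27l2a at -0.75 and Cd27 at -0.09. Immediate early and stress genes were higher in 10 of 11 cases, with a median of 0.51 (0.33 to 0.61), Hspa1b at 0.51 and Junb at 0.35. Acinar genes had a median of 0.27 (-0.41 to 1.22), although the 2 with the most UMIs were lower at 16 weeks, Clps with 17 against 25 UMIs and Prss2 with 5 against 22.

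Whether the lineages differ in stem-like and exhaustion genes was asked within each library, which removes differences between the libraries. Regulatory T-like cells and cells with a Foxp3 UMI were left out on the Cd4 side only. Cd8-gated cells had less Tcf7 (log2 ratio to conventional Cd4-gated cells -0.53 at 8 and -0.58 at 16 weeks) and less Slamf6 (-0.43 and -0.48), but more Bcl2, a survival gene (0.54 and 0.48). The stem-like and naive list as a whole had medians of -0.01 (-0.15 to 0.14) and -0.06 (-0.16 to 0.07). Exhaustion genes divided in the same way at both ages. Cd160 (2.23 and 2.85), Tnfrsf9, which encodes the costimulatory receptor 4-1BB (1.14 and 1.04), and Nr4a2 (1.41 and 0.78) were higher in Cd8-gated cells. Cd200 (-1.44 and -1.20), Tox2 (-0.77 and -1.01), Ctla4 (-0.34 and -0.69) and Pdcd1 (-0.10, -0.32 to 0.12, and -0.60, -0.93 to -0.29) were lower, Lag3 was at -0.21 and -0.13 and Tox at 0.05 and 0.07. The exhaustion medians were 0.11 (-0.15 to 0.32) and 0.21 (-0.07 to 0.47).

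The anergy markers were lower in Cd8-gated than in conventional Cd4-gated cells, Izumo1r by log2 ratios of -1.36 and -1.45 and Nt5e by -1.43 and -1.56, and the anergy list had medians of -0.44 (-0.75 to -0.21) and -0.64 (-1.11 to -0.30). Follicular helper genes (medians -2.46 and -1.95, Icos at -1.37 and -1.23) and costimulation genes (-2.35 and -1.87, Cd40lg at -3.14 and -4.23) were lower in Cd8-gated cells. Cytotoxic genes (2.67 and 2.30, Nkg7 at 2.99 and 2.98) and tissue residency genes (1.71 and 1.13, Xcl1 at 2.29 and 3.26) were higher in them. Izumo1r and Cd40lg were also fixed as markers of conventional CD4 T cells, and Nkg7 as one of CD8 T cells. Their differences between lineages therefore need not reflect anergy or another state. Th1 genes had medians of 0.40 and 0.05, with Ifng at -0.06 and -0.11, proliferation genes of 0.03 and -0.18, interferon response genes of 0.30 and 0.21, and immediate early and stress genes of -0.15 and -0.35. Set against all Cd4-gated cells, with regulatory cells included, the stem-like and naive medians turned to 0.16 and 0.23 and the exhaustion medians to -0.31 and -0.40. Other choices of cells and weights moved these medians as well: the 8-week stem-like and naive median was -0.16 with equal weight per cell, and the 16-week one -0.22 with the lineage taken from the majority of UMIs and 0.13 without cluster 5. The exhaustion median was 0.60 at 8 weeks under the majority gate and 0.64 at 16 weeks without cells that had 2 or more beta chains.

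**Figure D3:**
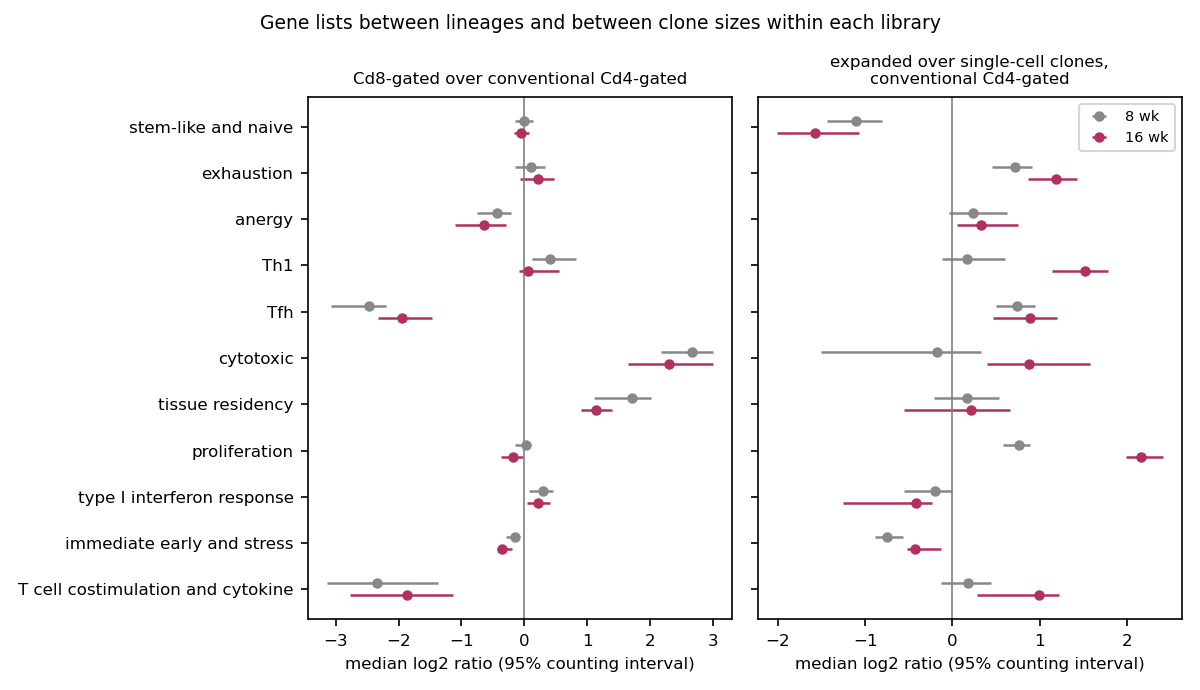
Median log2 ratios of 11 gene lists within each library, for Cd8-gated over conventional Cd4-gated cells (left) and for cells of expanded over single-cell clones among conventional Cd4-gated cells (right); points are medians over list members at 8 and 16 weeks and bars are 95% counting intervals. The stem-like and naive list lies at -0.01 and -0.06 on the left and at -1.11 and -1.58 on the right.

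Expanded clones, taken as 2 or more cells of 1 library and class with the same paired receptor nucleotide sequence, held a smaller share of the cells at 16 weeks. Of conventional Cd4-gated cells with a paired receptor, 74 of 444 were in expanded clones at 8 weeks (16.7%, 13.3 to 20.5%) and 31 of 431 at 16 weeks (7.19%, 4.94 to 10.1%). With equal numbers of cells drawn from each library, the difference was -9.26 percentage points (-13.6 to -4.98). Those 74 and 31 cells came from 26 and 15 clones, and the expanded Cd8-gated cells, given next, from 9 and 3. Intervals of expanded shares count cells as independent, although cells of 1 clone are expanded together, so they are too narrow. Of Cd8-gated cells, 25 of 212 were in expanded clones at 8 weeks (11.8%, 7.78 to 16.9%) and 6 of 225 at 16 weeks (2.67%, 0.985 to 5.71%), a difference of -9.30 points (-14.5 to -4.49) that was -3.21 points (-7.74 to 1.15) with the lineage taken from clusters. Over all T cells with a pair the shares were 14.7% (197 of 1336) and 7.09% (96 of 1354). For the shares by cluster, clones were counted over all T cells of a library, so the other cells of a clone could lie in other clusters. In follicular helper T-like cells 43.0% (36.6 to 49.6%) of paired cells at 8 weeks and 23.2% (17.0 to 30.4%) at 16 weeks were in expanded clones. Proliferating-like cells gave 30.5% and 24.6%, regulatory T-like cells 17.8% and 12.3%, and CD8 T-like cells 17.9% and 17.6%. None of the 299 and 423 paired naive or stem-like T-like cells was in an expanded clone, which allows shares of up to 1.00% and 0.709% (3 cells of the total). The number of mice pooled in each library is not given in the sources used here, and it affects how often 2 cells share a receptor.

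**Figure D4:**
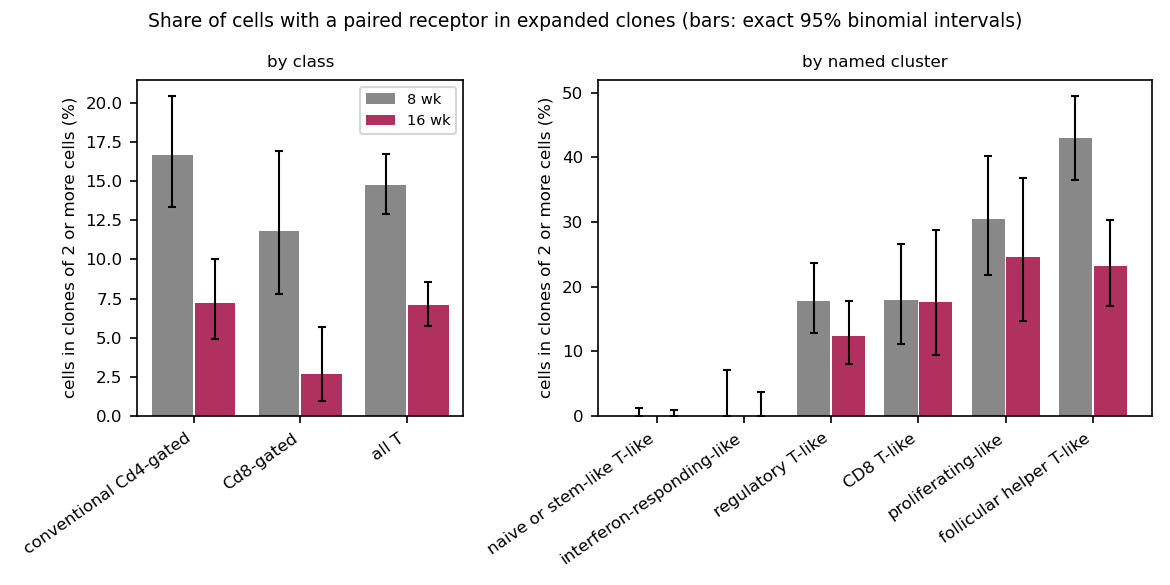
Share of cells with a paired receptor that lie in clones of 2 or more cells (vertical axis, percent) by class (left) and by named cluster (right) at 8 and 16 weeks; bars start at 0 and whiskers are exact 95% binomial intervals. Clones were counted within each class on the left and over all T cells of a library on the right. Follicular helper T-like cells have 43.0% and 23.2%, and naive or stem-like T-like cells 0 of 299 and 0 of 423.

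Conventional Cd4-gated cells of expanded clones had less RNA of most naive-type genes and more of most exhaustion and follicular helper genes than cells whose receptor was seen once, in both libraries. At 8 weeks (74 against 370 cells) Il7r stood at 31.1 against 170 CPM (-2.41), and at 16 weeks (31 against 400 cells) it differed by -2.20. Lef1 differed by -1.91 and -2.09, Klf2 by -1.39 and -1.01, and Satb1 had 1 and 3 UMIs in expanded cells. Tcf7 was close to even, at -0.15 (-0.49 to 0.17) and -0.24 (-0.73 to 0.19), Slamf6 was higher in expanded cells, at 0.22 (-0.13 to 0.55) and 0.87 (0.43 to 1.27), and Id3 stood at -0.48 and 1.53, with 47.4% of its 16-week UMIs in expanded cells from 1 cell. Pdcd1 was higher by 1.14 and 1.48, Lag3 by 1.30 and 1.26 (1 cell gave 38.3% of its 16-week UMIs in expanded cells), Cd200 by 1.27 and 0.82, Tigit by 0.72 and 1.14, and Tox by 0.72 and 0.64. The stem-like and naive medians were -1.11 (-1.44 to -0.81) and -1.58 (-2.01 to -1.07), and -1.07 at 16 weeks with Bach2, which had no UMI in expanded cells, set at 3 UMIs. The 16-week median was -0.98 over all Cd4-gated cells and -2.45 with clones of 3 or more cells. The exhaustion medians were 0.72 (0.45 to 0.92) and 1.19 (0.87 to 1.43). Cd200 and Tox2 of the exhaustion list were also among the leading genes of the follicular helper T-like cluster. Higher exhaustion genes and more follicular helper T-like cells therefore cannot be told apart here.

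Expanded cells were deeper, with median UMIs of 4758 against 3318 at 8 weeks and 4824 against 3176 at 16 weeks, and richer in cell division RNA, with proliferation medians of 0.77 and 2.16. For each proliferation gene, its highest cell gave from 23.1% (Birc5) to 51.5% (Rrm2) of the 16-week UMIs in expanded cells. Follicular helper genes had medians of 0.74 (0.50 to 0.95) and 0.89 (0.47 to 1.21), with Sh2d1a at 0.63 and 1.09, Tnfsf8 at 0.77 and 1.14, Cxcr5 at 0.98 and 1.91, and Il21, the gene of the main follicular helper cytokine, at 0.86 and 0.94. Immediate early and stress genes were lower, with medians of -0.75 and -0.42, although Nr4a1, a gene induced by receptor signalling, stood at 0.60 and 1.48. Ifng was higher in expanded cells by 0.99 and 1.52, and Tnf by 1.13 and 1.01. The Th1 medians were 0.17 (-0.12 to 0.60) and 1.52 (1.14 to 1.79). Ccl4 and Ccl3 had the largest 16-week ratios among Th1 genes, 5.00 and 5.25, and 1 cell gave 88.4% and 91.9% of their UMIs in expanded cells. Nt5e stood at 1.06 and 0.58 and Izumo1r at 0.22 and 0.33, with anergy medians of 0.24 and 0.33. The other medians were -0.18 (-0.32 with Klrk1 and Gzma, which had no UMI in expanded cells, set at 3 UMIs) and 0.88 for cytotoxic genes, 0.31 and -0.11 (0.35 with Ikzf4 set likewise) for the regulatory T cell list, 0.17 and 0.21 for tissue residency, -0.20 and -0.42 for interferon response and 0.18 and 1.00 for costimulation genes.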

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

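None of these differences was tested, since each rests on 1 library per age, and they were picked out because cells of the regulatory class went one way with age and cells of another class the other. Follicular helper genes had a median log2 ratio of 16 over 8 weeks of 0.39 in Foxp3-positive or regulatory T-like Cd4-gated cells and of -0.43 in conventional Cd4-gated cells, a gap of 0.82. In the regulatory class Maf stood at 257 against 196 CPM and Sh2d1a at 274 against 198, while Icos stood at 238 against 251. Th1 genes had medians of 0.33 in the regulatory class and -0.37 in Cd8-gated cells, a gap of 0.70, with Ccl5 at 1859 against 810 CPM in the regulatory class. Tissue residency genes had medians of 0.23 in the regulatory class, -0.31 in conventional Cd4-gated and -0.58 in Cd8-gated cells, gaps of 0.54 and 0.81. Lag3 was at 0.23 in the regulatory class, -0.57 in conventional Cd4-gated and -0.49 in Cd8-gated cells, gaps of 0.80 and 0.72. Izumo1r was at 0.21 in the regulatory class and -0.15 in conventional Cd4-gated cells, a gap of 0.36. The regulatory class had 176 and 154 cells. In its main cluster, led by Areg, Ctla4 and Foxp3, 39.6% of cells with a beta chain had 2 or more productive ones and the median depth was 5399.5 UMIs.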

How the results depend on the processing

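Of 238 alternative values, 215 lay inside the counting interval of the main value, 22 outside it and 1 had the opposite sign of a value whose interval excluded 0; settings marked as added were chosen after the data were seen, and the cause of a shift was not tested unless named. Under every one of these settings, the stem-like and naive medians of 16 over 8 weeks stayed above 0 (0.13 to 0.48 in conventional Cd4-gated and 0.19 to 0.38 in Cd8-gated cells), and the exhaustion medians below 0 (-0.52 to -0.22 and -0.51 to -0.16). The split of conventional Cd4-gated cells by naive-like clusters, given further below, was not among these settings and gave medians outside these ranges. The difference in expanded share stayed below 0 (-11.2 to -8.16 points in conventional Cd4-gated, -10.2 to -3.21 in Cd8-gated and -8.90 to -6.17 in all T cells).

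With equal weight per cell, the stem-like and naive median was 0.13 in conventional Cd4-gated cells (0.38 summed) and -0.16 for Cd8-gated over conventional Cd4-gated cells at 8 weeks (-0.01), and the exhaustion median for expanded over single cells was 1.03 at 8 (0.72) and 1.63 at 16 weeks (1.19). With regulatory cells kept, the Cd8-gated over Cd4-gated stem-like and naive medians were 0.16 and 0.23, the exhaustion medians -0.31 and -0.40, and the 16-week expanded stem-like and naive median -0.98 (-1.58); the regulatory cells had 516 and 528 CPM of Ctla4, against 91.2 and 97.0 in conventional Cd4-gated cells. With lineage from clusters, the expanded medians were -1.49 (-1.11) for stem-like and naive genes at 8 weeks and 1.12 and 1.53 for exhaustion at 8 and 16 weeks, the Cd8 exhaustion median by age was -0.16 (-0.38), and the Cd8 difference in expanded share -3.21 points (-9.30). With clones of 3 or more cells, the 16-week stem-like and naive median was -2.45. Without thinning, the Foxp3 difference was -2.87 points (0.04).

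Among the added settings, the majority gate gave a 16-week Cd8-gated over conventional Cd4-gated stem-like and naive median of -0.22 (-0.06) and an 8-week exhaustion median of 0.60 (0.11). Leaving out cluster 5 gave 0.13 for the former. Leaving out cells with 2 or more beta chains gave 16-week exhaustion medians of 0.64 (0.21) for Cd8-gated over conventional Cd4-gated and 0.86 (1.19) for expanded over single cells. With library means removed before clustering, the age difference in the interferon-responding-like share was -0.44 points, against 3.05, and in the CD8 T-like share -0.925 points, against -2.81. No paired analysis was possible because each age has 1 library of each kind. Depth limits genes such as Havcr2, with 10 UMIs over both libraries in conventional Cd4-gated cells, and Th17 genes.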

Other observations

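Regulatory cells (Cd4-gated with a Foxp3 UMI or in a regulatory T-like cluster) also had higher naive-type and lower cell division RNA at 16 weeks, in a class of which 73.9% and 83.1% of cells at 8 and 16 weeks were regulatory T-like and 13.1% and 8.44% proliferating-like, the cluster with a median of 14295.5 UMIs. All 13 stem-like and naive genes were higher (median 0.39, 0.27 to 0.56), led by Lef1 at 0.73, with Tcf7 at 0.34 and Slamf6 at 0.39, and all 12 proliferation genes were lower (-0.72, -0.94 to -0.53), with Hmgb2 at -0.48. Exhaustion genes had a median of -0.07 (-0.22 to 0.05): Pdcd1 stood at 178 against 263 CPM (-0.56), Ctla4 differed by 0.03 and Tox by 0.05. Anergy genes had a median of 0.18 (0.01 to 0.39), with Nt5e at 0.53, and regulatory T cell genes one of -0.20 (-0.36 to -0.08), with Foxp3 at 0.04, Tnfrsf4 at -0.30 and Il2ra, the interleukin 2 receptor gene, at -0.55. Cytotoxic, interferon and costimulation genes had medians of 0.02, -0.10 and 0.07, with Nkg7 at -0.55, Ifi27l2a at -0.31 and Cd27 at -0.13. Immediate early and stress genes had a median of 0.52 (0.38 to 0.62), with Junb at 0.36.

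Expanded clones often spanned clusters. Of 64 expanded clones at 8 weeks 48 had a follicular helper T-like cell and 22 of these also a regulatory T-like one, and at 16 weeks 10 of the 24 with a follicular helper T-like cell did, of 37 in all. With cells of 1 beta chain only, the counts were 17 of 40 and 9 of 22. No 8-week clone and 3 16-week clones joined follicular helper T-like and CD8 T-like cells. The CD8 T-like cluster held 34 Cd4-gated beside 136 Cd8-gated cells, so a clone that joined these clusters need not span the lineages. By the gates, 3 of 47 clones at 8 weeks and 0 of 24 at 16 weeks with 2 or more gated cells held both lineages. The largest clone had 14 cells at 8 weeks, 10 of them follicular helper T-like, with TRAV21-DV12 and TRBV13-2, and the largest at 16 weeks had 7 cells with TRAV14-1 and TRBV15. The TRAV11-TRAJ18 alpha chain of invariant NKT cells was found in 5 of 1336 paired cells at 8 weeks (0.374%) and in 0 of 1354 at 16 weeks, which allows up to 0.222%.

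Markers of other cells were scarce in conventional Cd4-gated cells, where summed levels at 8 and 16 weeks were 2.99 and 1.79 CPM for islet endocrine genes (Ins2), 15.7 and 12.5 for B cell genes (Cd74, Cd79b), 0.0 and 6.70 for dendritic genes (Itgax) and 8.22 and 1.34 for NK-type genes (Ncr1). Endothelial and stromal genes gave 38.5 and 45.1 CPM, from Pecam1, and Th17 genes 1.12 and 3.13 CPM, from Il1r1, while no erythroid gene reached 10 UMIs. Myeloid genes had a median of -0.07 (-1.33 to 0.10), with Cst3 at 187 against 196 CPM. In the regulatory class the 3 measured myeloid genes had a median of 0.81 (0.002 to 2.04), and acinar genes one of 0.25 (-0.20 to 0.75). Summed levels there at 8 and 16 weeks were 9.10 and 38.0 CPM for islet endocrine and 9.92 and 30.4 for endothelial and stromal genes. B cell genes gave 74.4 and 85.6 CPM. In these lists only members with 10 or more UMIs were counted.

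Of the tests that follow, the comparison of nucleotides of shared receptors was chosen only after its result was seen. The higher naive-type and lower exhaustion RNA of conventional Cd4-gated cells at 16 weeks was weighed against handling stress, cell makeup and the Cd4 gate. With 468 cells per age matched on their share of stress UMIs, the stem-like and naive median was 0.26 (0.13 to 0.41), with the stress median at 0.04. The exhaustion median in these cells was -0.39 (-0.57 to -0.26). RNA of the listed stress genes is thus not the whole cause in these libraries, but matching does not cover effects of handling on other genes. With lineage from clusters, each set by the majority of its gated cells, the stem-like and naive median was 0.35 (0.29 to 0.47). The need for a Cd4 UMI in each cell is thus not the whole cause for that list. Outside the naive or stem-like T-like clusters the stem-like and naive median was 0.38 (0.17 to 0.52) and inside them -0.12 (-0.30 to 0.08), but those clusters were named by genes of the same list, and the interferon-responding-like cells outside them were 20 of 409 at 8 weeks and 38 of 308 at 16 weeks, so a larger share of naive-like cells and a difference within cells cannot be told apart. For the exhaustion list, cell makeup may account for the difference: outside the naive-like clusters its median was -0.001 (-0.22 to 0.21). Age itself, and a larger weight of deep dividing cells at 8 weeks (0.13 with equal weight per cell), stay open.

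The smaller share of cells in expanded clones at 16 weeks was weighed against doublets, 1 large clone and cell makeup. Over all T cells the difference was -7.96 points (-10.4 to -5.50) without cells with 2 or more beta chains. It was -7.31 (-9.62 to -5.02) without the largest clone of each library and -7.95 (-11.1 to -4.79) outside the naive-like clusters. None of these alone removed the difference between these libraries. The intervals count cells of 1 clone as independent and are too narrow, so they do not show how firmly each is excluded as the whole cause. With clones counted only among cells of the follicular helper T-like cluster, and equal numbers drawn, 29.4% and 15.9% of cells were in expanded clones, a difference of -13.5 points (-22.3 to -4.49). The number and mix of mice in each library may set these shares, was not tested, and stays open beside age.

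Of the paired receptors, 4 had the same amino acids in both libraries: 7 and 3 cells with TRAV16N and TRBV15, 14 and 1 with TRAV21-DV12 and TRBV13-2, 2 and 2 with TRAV5-4 and TRBV1, and 1 and 1 with TRAV16N and TRBV13-1. A share of 0.25 of them, the TRAV5-4 receptor, also had the same nucleotides, so that carry-over of a clone between the libraries and the same receptor arising in different mice cannot be told apart for it, with 1 receptor too few to decide. The cells of that receptor shared 0 cell barcodes between the libraries, which argues against index hopping. No biological explanation was tested.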
